A study of Mus musculus with 18 samples.

How the data were processed

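RNA was measured on 18 Affymetrix arrays, 9 of mouse cerebral cortex and 9 of primary cultures of mouse cortical cells. Each system held 3 groups of 3 arrays. Per the labels' protocols, the cortex samples came from 27 male C57BL/6J mice, 9 per group, and the RNA of 3 mice of a group was pooled for each array. The cultures were 9 dishes of 3 different cultures, prepared from C57BL/6J cortices of newborn pups or of embryos (E16 to E18). Every array received 100 ng of total RNA, labelled with a whole-transcript sense protocol. Cortex RNA and culture RNA were isolated with different kits, per the labels' protocols.

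The deposited table holds log2 values that the authors made with RMA (robust multi-array average, which corrects background, normalizes arrays and summarises the probes of a probe set), per the submitters' processing notes. The RMA version and settings are not given in the sources used here, and neither is whether cortex and culture arrays were normalized together. The medians of the 18 columns lay between 6.87 and 7.09. The standard deviation across probe sets lay between 2.29 and 2.31 on cortex arrays and between 2.77 and 2.80 on culture arrays, so the systems did not share one distribution. Each system was fitted on its own, and comparisons across systems were repeated after quantile normalization. After scaling each array to a common standard deviation, only the response differences of immediate early and effector genes and of glucocorticoid-responsive genes were recomputed. The number of arrays limits the precision of all values.

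The table had 23238 probe sets. In the platform annotation, 14939 had 1 gene symbol, 989 had several and 7310 had none. Symbols were looked up by Entrez ID in a RefSeq table, of assembly GRCm38.p6, used for names alone; 14884 probe sets matched and 0 symbols changed. For each of 131 genes with more than 1 probe set, the probe set with the highest mean over the 18 arrays was kept, which gave 14807 genes. No gene was removed for low signal. Probe sets with no single gene symbol were tested apart and not named.

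Differences between groups were tested with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, two-sided), with Benjamini-Hochberg adjustment over the 14807 genes of each comparison. A gene is said to have risen, fallen or changed where its adjusted p was under 0.05. Errors of fold changes are standard errors of the fit, and n is 3 arrays per group unless stated. The 3 comparisons within each system used the 9 arrays of that system. The comparison of untreated cultures with untreated cortex, and the test of whether the response differed between systems (the interaction), used 1 model of 6 groups over all 18 arrays. Genes that changed in both systems were counted and set against chance with Fisher's exact test (two-sided). The correlation of responses across genes was tested by exact relabelling of arrays within each system, with 400 relabellings that treat dishes as exchangeable; a relabelling within same-number dishes, and simulations of shared arrays with effects, were added after the results were seen.

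Changes of gene lists were tested with camera of limma (preset correlation between genes of 0.01), adjusted over 31 lists in each comparison. Camera asks whether the genes of a list shifted more than the other genes. It was repeated with the correlation estimated from the residuals of each list, and fry of limma, which asks whether a list's genes move one way on balance, was run beside it. There were 18 pathway lists and 13 lists of cell type markers, written from general knowledge. Members that changed were counted over all genes and adjusted over the list alone.

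The genes named below follow a rule. In sleep deprivation against control, and stimulation against sham, they are the 10 changed genes with the largest rise and the 10 with the largest fall. In each other comparison they are the 5 and 5 with the largest changes. Anchor genes were named in every comparison: Fos, Arc, Egr1, Homer1, Bdnf, Nptx2, Per1, Per2, Dbp, Hspa5 and Cirbp; Per2 had no singly named probe set. Members of a described list could be named if they changed or were among the 4 with the smallest p, but not all such members are named. For recovered against control cortex, clock genes with an unadjusted p under 0.05 are also named, a choice made after the results were seen. The grouping, comparisons, tests, gene lists, naming rule and most alternatives were chosen before the data were examined.

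The labels number the replicates of each group. In the cultures, arrays with the same number deviated together from their group means, with correlations of 0.202 to 0.552 over 9 pairs, against -0.358 to 0.118 over 18 pairs with different numbers. The pairing rests on this check of the data and on the labels, which speak of 9 dishes of 3 cultures. The planned fit had no replicate block, and the value with the block is given beside culture results where it changed a call or moved a count by more than 1.5 times.

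The alternatives were leaving out the 30% of genes with the lowest mean, testing every singly named probe set, quantile normalization, an intensity trend with robust variance, array weights, a replicate block, all 18 arrays in 1 model or fewer arrays in the fit, an estimated correlation for the lists, and leaving out each array in turn. The gene and list tests were tested on simulated data made from the means and spread of the real arrays, with 50 genes changed per fold size. Genes were drawn independently of each other and without the shared deviations of same-number dishes. The false calls below therefore need not hold for the real arrays. For sleep deprivation against control, the share recovered was 70% at 1.25-fold, 80% at 1.5-fold and 96% at 2-fold, with 6 false calls among 14584 unchanged genes. For stimulation against sham in culture, it was 26%, 32% and 86%, with 8 false calls. For culture against cortex it was 42%, 82% and 98%, with 30 false calls (14.4% of calls), and for the interaction 20%, 44% and 78%, with 10 false calls. Figures were drawn with matplotlib 3.10.9 under Python 3.11.15.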

Results

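Gene expression was measured in mouse cortex and in cortical cultures, each at rest, after a treatment and after recovery. Cortex was taken from undisturbed home-cage mice, from mice kept awake for 6 h, and from mice that recovered after the 6 h of sleep deprivation. The source labels give 18 h of recovery, the treatment protocol gives 24 h, and the design places the sampling on the next day at the clock time when deprivation had begun. Cultures were sampled 3 h after a sham stimulation with water, 3 h after a cocktail of excitatory neurotransmitters, and 24 h after that stimulation. Each of the 6 groups had 3 arrays, where a cortex array is a pool of 3 mice and a culture array is a dish. The p-values therefore measure the spread between these pools and dishes alone. Pearson correlations between arrays of 1 group lay between 0.979 and 0.993, and those between a cortex and a culture array between 0.920 and 0.937.

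The first comparison asked which cortical transcripts changed during 6 h of enforced wakefulness. The transcript with the largest rise was Arc (Entrez 11838), a synaptic gene induced by neuronal activity. Its log2 signal was 8.84 ± 0.07 in control cortex and 10.39 ± 0.08 after sleep deprivation (SD, n = 3), a 2.94-fold rise (log2 1.56 ± 0.05, adjusted p = 2.3e-05). The transcription factor Egr2 rose by 1.28 ± 0.07 on the log2 scale (adjusted p = 2.2e-04), and the nuclear receptor Nr4a1 by 0.99 ± 0.10 (adjusted p = 0.0056). Hspa5, the main chaperone of the endoplasmic reticulum, rose 1.74-fold (log2 0.80 ± 0.07, adjusted p = 0.0037). In the other direction, the cold-inducible RNA-binding protein gene Cirbp changed by -0.74 ± 0.08 (adjusted p = 0.0063), and Dcx, a microtubule gene of young neurons, by -0.62 ± 0.03 (adjusted p = 2.2e-04). In all, 241 of 14807 genes changed, 107 higher and 134 lower, of which 24 rose and 9 fell by at least 1.5-fold. After quantile normalization 170 were higher and 161 lower, 51.4% higher in place of 44.4%, so the surplus of falls was lost.

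Other large rises in sleep-deprived cortex were those of Cdkn1a (log2 0.87 ± 0.07), a cell cycle inhibitor, Sdf2l1 (0.82 ± 0.07), a component of the endoplasmic reticulum chaperone complex, and Dusp4 (0.80 ± 0.09), a phosphatase of MAP kinases. Tm6sf2 (0.74 ± 0.04) and the melanocortin receptor gene Mc4r (0.71 ± 0.09) followed, with Olfr1444 (0.80 ± 0.10), a member of the large olfactory receptor family. The largest falls were those of Cd180 (-1.06 ± 0.08), a surface receptor of immune cells, Cstad (-1.004 ± 0.12) and the oligodendrocyte gene Opalin (-0.84 ± 0.06). Pla2g4e (-0.75 ± 0.08), which encodes a cytosolic phospholipase, Ankrd34c (-0.67 ± 0.11), the parathyroid hormone receptor gene Pth2r (-0.59 ± 0.09), Rasl11b (-0.59 ± 0.05) and Sytl2 (-0.57 ± 0.03) also fell. Adjusted p for these genes lay between 2.2e-04 for Sytl2 and 0.032 for Ankrd34c.

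**Figure D1:**
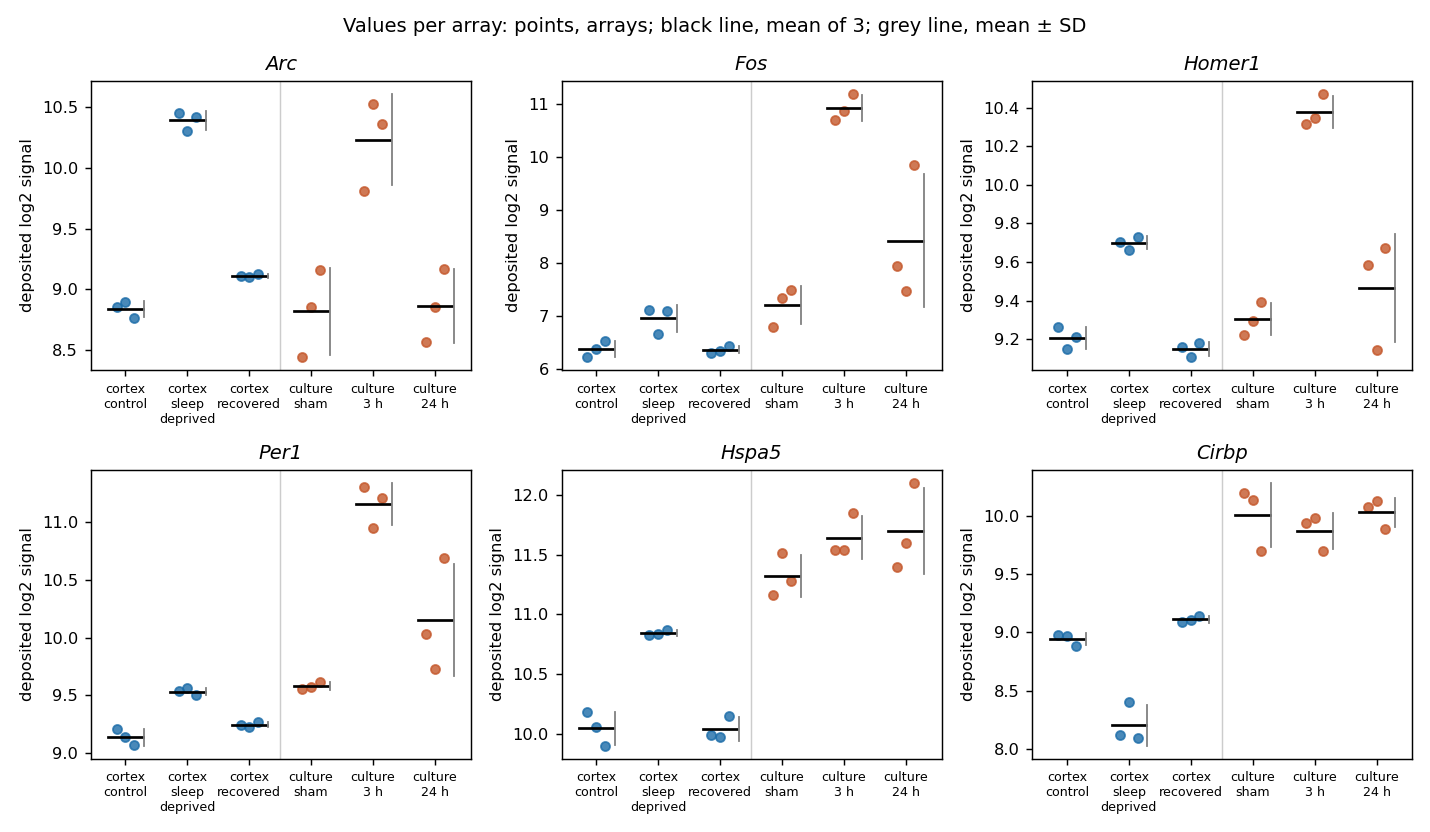
Deposited log2 signal (y axis) of Arc, Fos, Homer1, Per1, Hspa5 and Cirbp in the 6 groups, with cortex in blue and culture in orange; points are arrays, black lines means of 3 arrays and grey lines mean ± SD. Arc means rise from 8.84 to 10.39 in sleep-deprived cortex and from 8.82 to 10.23 in stimulated culture.

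Activity-regulated effector genes rose as a group in sleep-deprived cortex. Of 26 measured, 9 rose over all genes and 17 adjusted over the list alone, with a median of 0.25 (camera adjusted p = 3.1e-19; adjusted p = 0.026 with an estimated correlation). Homer1 (0.49 ± 0.04), Nptx2 (0.37 ± 0.06), the MAP kinase phosphatase genes Dusp1 (0.64 ± 0.03) and Dusp6 (0.65 ± 0.11), the kinase gene Sik1 (0.62 ± 0.06), Gpr3 (0.61 ± 0.06) and Trib1 (0.64 ± 0.09) were among them. Bdnf, which encodes a growth factor, did not pass (0.21 ± 0.06, adjusted p = 0.19). Of 21 immediate early transcription factors, 7 rose over all genes and 12 adjusted over the list alone, with a median of 0.22 (camera adjusted p = 3.9e-13; adjusted p = 0.056 with an estimated correlation). Besides Egr2 and Nr4a1 these were Egr1 (0.37 ± 0.04), Nr4a3 (0.51 ± 0.07), Fosl2 (0.51 ± 0.08), Junb (0.41 ± 0.06) and Npas4 (0.22 ± 0.03). Fos was higher by 0.58 ± 0.12 and did not pass (adjusted p = 0.080).

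Chaperones of the endoplasmic reticulum and the unfolded protein response also rose. Of 24 measured, 9 rose over all genes and 13 adjusted over the list alone (median 0.24, camera adjusted p = 5.1e-14; adjusted p = 0.0040 with an estimated correlation). They included the protein disulfide isomerases Pdia4 (0.51 ± 0.06) and Pdia6 (0.46 ± 0.07), the chaperone genes Calr (0.30 ± 0.04), Hsp90b1 (0.35 ± 0.06) and Hyou1 (0.32 ± 0.06), the transcription factor Xbp1 (0.39 ± 0.05) and Manf (0.44 ± 0.07). Of 16 cytosolic and mitochondrial chaperones, 3 rose (Dnajb5 by 0.51 ± 0.04, Chordc1 by 0.38 ± 0.03 and Hsph1 by 0.33 ± 0.06) and 9 adjusted over the list alone (median 0.17, camera adjusted p = 1.4e-09; adjusted p = 0.055 with an estimated correlation). Of 21 glucocorticoid-responsive genes, 8 rose and 13 adjusted over the list alone (median 0.32, camera adjusted p = 4.3e-16; adjusted p = 0.017 with an estimated correlation). Besides Cdkn1a these were Tsc22d3 (0.69 ± 0.08), Plin4 (0.68 ± 0.09), Fkbp5 (0.64 ± 0.11), which encodes a co-chaperone of the glucocorticoid receptor, Hif3a (0.47 ± 0.08), Sgk1 (0.41 ± 0.06), Mertk (0.32 ± 0.06) and Errfi1 (0.21 ± 0.04). Cholesterol synthesis genes shifted down by a small median of -0.08 (camera adjusted p = 0.024; adjusted p = 0.89 with an estimated correlation). None of the 19 measured passed over all genes and 3 were lower adjusted over the list alone. The 3 with the smallest p were Insig1 (-0.24 ± 0.06, adjusted p = 0.097), Hmgcs1 (-0.22 ± 0.06) and Lss (-0.25 ± 0.07). The next by p, Pmvk, went the other way (0.16 ± 0.07, adjusted p = 0.36).

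Clock genes moved both ways in sleep-deprived cortex: of 18 measured, the period gene Per1 (0.39 ± 0.04) and the repressor Bhlhe40 (0.46 ± 0.06) rose, Dbp (-0.53 ± 0.07) and Usp2 (-0.36 ± 0.04) fell, and 14 did not pass (camera adjusted p = 0.27). The labels do not give the clock time at which control mice or sham cultures were sampled, so time of day was not separated from treatment. Among markers of cell types, Opalin and Aspa (-0.33 ± 0.04) fell of 12 oligodendrocyte genes, Trem2 (-0.32 ± 0.04) fell of 14 microglial genes, and Dcx fell of 11 genes of immature neurons. None of the measured markers of astrocytes (12, median 0.038), oligodendrocyte precursors (9, 0.042), interneurons (12, 0.021), neurons (12, -0.0043), endothelial cells (14, -0.022) or pericytes (14, -0.051) passed. The same held for blood cells (7, 0.034), choroid plexus (8, 0.050), dividing cells (15, 0.035), and striatum and hippocampus (9, -0.056). Among pathways, none of 24 respiratory chain genes (-0.022), 16 protein synthesis factors (0.022), 23 presynaptic genes (-0.0083), 22 postsynaptic genes (1.6e-04) or 24 inflammatory genes (0.0060) passed. The means of neurons (0.012), oligodendrocyte precursors (-5.4e-04) and inflammatory genes (-0.017) had the opposite sign to their medians. Cirbp was the only 1 of 17 RNA-binding protein genes to pass, and Pla2g4e the only 1 of 32 phospholipid genes; limma was the test for all of these lists, and camera called none of them. The count of 241 depended on the fit and on single arrays. It was 31 with all 18 arrays in 1 model, 94 with only the 6 compared arrays, 140 with the replicate block, 380 without the 30% of genes with the lowest mean and 811 with array weights. It was 119 without control pool 1, 72 without control pool 2, and 77, 99 and 85 without sleep-deprived pools 1, 2 and 3.

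**Figure D2:**
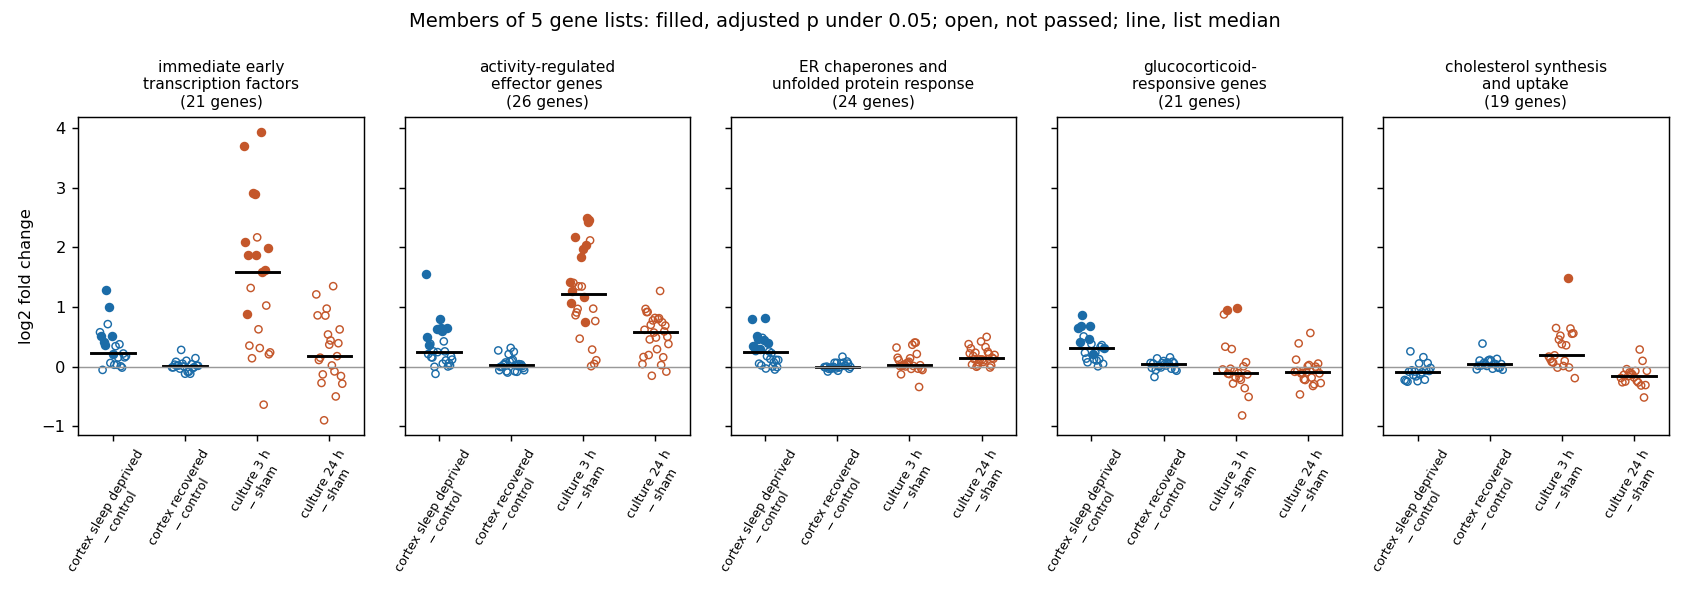
Log2 fold change (y axis) of the measured members of 5 gene lists in 4 comparisons; points are genes, filled where adjusted p was under 0.05, and lines are list medians. Effector genes have a median of 0.25 in sleep-deprived cortex and 1.22 in stimulated culture, and glucocorticoid-responsive genes 0.32 and -0.11.

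The second comparison asked which of these changes remained on the next day. In recovered against control cortex, limma called 0 of 14807 genes (smallest adjusted p = 0.096), with 427 genes at an unadjusted p under 0.05 where 740 would be expected by chance. Arc was 0.27 ± 0.05 above control on the log2 scale, with recovered arrays at 9.11 ± 0.01 and control arrays at 8.84 ± 0.07 (SD, n = 3). In limma its adjusted p was 0.90 and its unadjusted p 6.1e-04, so a remaining difference of Arc stays open. Differences from control were -0.01 ± 0.07 for Hspa5, 0.17 ± 0.08 for Cirbp, 0.11 ± 0.04 for Per1 and 0.20 ± 0.07 for Dbp, and none passed. Fos (-0.01 ± 0.12), Egr1 (0.02 ± 0.04), Homer1 (-0.06 ± 0.04), Bdnf (-0.0037 ± 0.06) and Nptx2 (-3.1e-05 ± 0.06) did not pass either. Of the other clock genes named by the rule above, Per3 (0.18 ± 0.04), Tef (0.13 ± 0.05) and Cry1 (0.08 ± 0.04) lay above control. Clock (-0.08 ± 0.03) lay below it, and none of them passed. Camera and fry called 0 of 31 lists. The 107 genes that had risen with sleep deprivation had a median of 0.026 against control after recovery, and the 134 that had fallen a median of -0.0013. Both comparisons share the control arrays. In 50 simulations with recovered arrays at the control level and genes independent of each other, these medians lay between -0.0136 and 0.0212, and between -0.0163 and 0.0035. The value of 0.026 is just above its range, which is too narrow because real genes vary together.

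Recovered cortex differed from sleep-deprived cortex in 334 genes, 217 higher and 117 lower. By the design, recovered mice were sampled at the clock time when deprivation began, and sleep-deprived mice after 6 h of it. By that account time of day differs between these groups and was not separated from recovery. The 24 h of the treatment protocol, if counted from the end of deprivation, would give both groups the same clock time. Arc (-1.28 ± 0.05, adjusted p = 1.0e-04), Egr2 (-1.26 ± 0.07), Cdkn1a (-1.04 ± 0.07), Hspa5 (-0.81 ± 0.07) and Dio2 (-0.78 ± 0.09), which encodes a thyroid hormone deiodinase, had the largest falls. Cstad (1.14 ± 0.12), Cd180 (1.06 ± 0.08), Cirbp (0.91 ± 0.08), the methyltransferase gene Inmt (0.89 ± 0.05, adjusted p = 4.1e-04) and Opalin (0.81 ± 0.06) had the largest rises. Homer1 (-0.55 ± 0.04), Egr1 (-0.35 ± 0.04), Nptx2 (-0.37 ± 0.06) and Per1 (-0.29 ± 0.04) fell and Dbp rose (0.73 ± 0.07); Fos (-0.59 ± 0.12, adjusted p = 0.059) and Bdnf (-0.22 ± 0.06, adjusted p = 0.15) did not pass. Dcx (0.66 ± 0.03), Aspa (0.36 ± 0.04) and Trem2 (0.30 ± 0.04) rose. Of the 241 genes that changed with sleep deprivation, 199 changed in the opposite direction here, 86 of them falling and 113 rising. Independent lists of these sizes would share 2.81, and both comparisons share the sleep-deprived arrays, so part of the excess may come from these. Simulated arrays without effects gave 0 opposite calls in 50 simulations, which is uninformative because they give hardly any calls. With the observed effects and recovered arrays kept at the sleep-deprived level, the mean was 0.04 and the highest 1.

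The lists that had risen fell from sleep deprivation to recovery. Effector genes fell (8 of 26, and 15 adjusted over the list alone; median -0.20, camera adjusted p = 5.1e-18; adjusted p = 0.030 with an estimated correlation), as did endoplasmic reticulum chaperones (9 of 24, and 12; -0.19, 3.5e-13; adjusted p = 0.0047 with an estimated correlation). Glucocorticoid-responsive genes fell (7 of 21, and 10; -0.25, 3.0e-13; adjusted p = 0.028 with an estimated correlation). Immediate early transcription factors fell (8 of 21, and 11; -0.33, 3.7e-12; adjusted p = 0.067 with an estimated correlation), with Egr3 (-0.75 ± 0.14) among them. Cytosolic chaperones fell (3 of 16, and 6; -0.16, 2.7e-09; adjusted p = 0.059 with an estimated correlation). Cholesterol synthesis genes shifted up (median 0.12, camera adjusted p = 0.0055; adjusted p = 0.75 with an estimated correlation), with Insig1 (0.36 ± 0.06), a regulator of sterol synthesis, and the synthase gene Lss (0.35 ± 0.07) rising of 19. After quantile normalization the split was 245 higher and 238 lower, so the surplus of rises, 65.0% of calls, became 50.7%. The count of 334 was 42 with all 18 arrays in 1 model, 182 with only the 6 compared arrays, 190 with the replicate block, 608 without the 30% of genes with the lowest mean and 774 with array weights. It was 127, 215 and 173 without recovered pools 1, 2 and 3, and 104, 145 and 111 without sleep-deprived pools 1, 2 and 3.

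The third comparison asked what had changed in cultured cortical cells 3 h after excitatory stimulation. The stress-induced transcription factor Atf3 had the largest rise, 15.3-fold (log2 3.94 ± 0.47, adjusted p = 0.014), from 7.0 ± 0.21 in sham to 10.94 ± 0.48 in stimulated dishes (SD, n = 3). Fos rose 12.99-fold (3.70 ± 0.54, adjusted p = 0.024), and Gadd45b, a gene of the DNA damage and demethylation response, rose by 2.46 ± 0.14 with the smallest adjusted p of these genes (9.6e-04). Arc rose by 1.41 ± 0.25 (adjusted p = 0.041), and Bdnf by 1.27 ± 0.20 (adjusted p = 0.027). The transcript with the largest fall was Nrarp (-1.46 ± 0.24, adjusted p = 0.037), a regulator of Notch signalling. In all, 215 genes changed, 133 higher and 82 lower, of which 113 rose and 30 fell by at least 1.5-fold.

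Tnfaip6 (3.03 ± 0.36), the nuclear receptors Nr4a1 (2.91 ± 0.41) and Nr4a2 (2.89 ± 0.33), the kinase gene Pim1 (2.49 ± 0.19), the clock output repressor Nfil3 (2.49 ± 0.41), the prohormone convertase gene Pcsk1 (2.42 ± 0.36) and the telomere protein gene Tinf2 (2.28 ± 0.30) completed the 10 largest rises. The falls continued with the sulfotransferase gene Chst12 (-1.32 ± 0.11), Dnajc28 (-0.95 ± 0.18), Lrtm2 (-0.94 ± 0.16), Pik3ip1 (-0.90 ± 0.13), the pericyte receptor gene Pdgfrb (-0.89 ± 0.10), Crebl2 (-0.82 ± 0.15) and Oxsm (-0.79 ± 0.09). Olfr61 (-0.89 ± 0.12) and Olfr1102 (-0.85 ± 0.13), of the olfactory receptor family, also fell. Homer1 (1.07 ± 0.13) and Per1 (1.58 ± 0.22) rose. Egr1 (0.35 ± 0.28, adjusted p = 0.79), Nptx2 (1.404 ± 0.39, adjusted p = 0.14), Hspa5 (0.32 ± 0.18, adjusted p = 0.60), Cirbp (-0.14 ± 0.15, adjusted p = 0.90) and Dbp (-0.68 ± 0.21, adjusted p = 0.20) did not pass.

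Activity-regulated genes formed the largest shifts of the 31 lists in culture. Of 26 effector genes, 12 rose over all genes and 21 adjusted over the list alone (median 1.22, camera adjusted p = 9.8e-32; adjusted p = 0.11 with an estimated correlation). The activin subunit gene Inhba (2.18 ± 0.26), Gpr3 (2.04 ± 0.28), Dusp1 (1.98 ± 0.37), Sik1 (1.85 ± 0.25), Dusp4 (1.17 ± 0.20) and Dusp6 (0.74 ± 0.14) were among them. Of 21 immediate early transcription factors, 11 rose over all genes, and 16 rose and 1 fell adjusted over the list alone (median 1.59, camera adjusted p = 1.9e-23; adjusted p = 0.11 with an estimated correlation). Fosl2 (2.09 ± 0.32), Csrnp1 (1.99 ± 0.24), Nr4a3 (1.88 ± 0.31), Junb (1.87 ± 0.26), Maff (1.62 ± 0.23), Klf4 (1.59 ± 0.20) and Jun (0.88 ± 0.14) rose besides those above. With the replicate block Npas4 rose too.

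Glucocorticoid-responsive genes did not shift as a group in stimulated culture (median -0.11, camera adjusted p = 0.58), though Errfi1 (0.99 ± 0.08) and Cdkn1a (0.95 ± 0.12) rose of 21. Adjusted over the list alone 3 were higher and 1 lower. With the replicate block Sgk1, which rose in sleep-deprived cortex, rose in culture too. No endoplasmic reticulum chaperone of 24 passed, and the small shift of the list (0.03, camera adjusted p = 0.027) was lost, with adjusted p = 0.86 with an estimated correlation. Cytosolic chaperones shifted by 0.11 (camera adjusted p = 0.0070; adjusted p = 0.59 with an estimated correlation); 0 of 16 passed in limma, and with the replicate block Dnajb4 (0.79 ± 0.20, adjusted p = 0.11; 0.023 with the block) and Bag3 (1.51 ± 0.53, adjusted p = 0.26; 0.045 with the block) did. Cholesterol synthesis genes shifted up (0.19, camera adjusted p = 1.2e-04; adjusted p = 0.72 with an estimated correlation), with Pmvk the 1 of 19 to pass (1.49 ± 0.28, adjusted p = 0.049; 0.062 with the block). Smaller upward shifts were called for neuronal markers (0.06, adjusted p = 0.0070, and adjusted p = 0.37 with an estimated correlation) and inflammatory genes (0.06, 0.013, and adjusted p = 0.50 with an estimated correlation). The same held for markers of striatum and hippocampus (0.10, 0.015, and adjusted p = 0.24 with an estimated correlation) and glycolysis genes (0.04, 0.018, and adjusted p = 0.37 with an estimated correlation). Of 18 clock genes, Per1, Nfil3 and Usp2 (0.83 ± 0.13) rose.

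The pairing of dishes raised the culture count to 358 with a replicate block (195 higher and 163 lower), 186 of them shared with the 215, and camera then also called interneuron markers (adjusted p = 0.0070; 0.37 with an estimated correlation). After quantile normalization 193 genes were higher and 70 lower, a share higher of 73.4% in place of 61.9%. All 18 arrays in 1 model gave 1170 genes, and array weights 910. Without sham dishes 1, 2 and 3 the count was 18, 38 and 20, and without stimulated dishes 1, 2 and 3 it was 34, 72 and 30.

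The fourth comparison followed the stimulated cultures to 24 h. Sham dishes were sampled at 3 h alone, so time in the dish was not separated from stimulation here. The comparison of 24 h with 3 h after stimulation has no sham of 24 h beside it either. Against sham at 3 h, limma called 0 genes (smallest adjusted p = 0.37), with 877 at an unadjusted p under 0.05 where 740 would be expected; the block gave 0 and 1544. The 0 depended on the fit. All 18 arrays in 1 model, which gives cortex and culture 1 shared spread per gene, gave 64 genes, and array weights gave 958. Fos was 1.21 ± 0.54 above sham on the log2 scale (adjusted p = 0.84), with dishes at 7.95, 7.47 and 9.85. Arc (0.04 ± 0.25) and Homer1 (0.16 ± 0.13) lay close to sham, Bdnf was 0.62 ± 0.20, Per1 0.57 ± 0.22, Dbp 0.89 ± 0.21, Nptx2 0.97 ± 0.39, Hspa5 0.38 ± 0.18, Cirbp 0.02 ± 0.15 and Egr1 -0.27 ± 0.28, none past the test. Without sham dish 2 or dish 2 of the 24 h group, 1 gene passed. The 133 genes that had risen at 3 h had a median of 0.19 above sham at 24 h, and the 82 that had fallen a median of -0.13. Both comparisons share the sham dishes, which pull the values the same way. In 50 simulations with 24 h dishes at the sham level and genes independent of each other, these medians lay between -0.025 and 0.059, and between -0.035 and 0.0067. The sign of the change was kept by 87.2% of the risen and 95.1% of the fallen genes, where the simulations gave at most 63.7% and 73.7%. All these values lie beyond the simulated ranges, but real genes vary together, so the ranges are too narrow and a remaining response was not established.

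Camera called 3 lists higher at 24 h than in the sham dishes of 3 h. They were effector genes (median 0.58, 4 of 26 higher adjusted over the list alone, adjusted p = 1.5e-11), endoplasmic reticulum chaperones (0.14, adjusted p = 3.4e-05) and markers of dividing cells (0.25, adjusted p = 9.5e-05), each with adjusted p = 0.92 with an estimated correlation. The effector genes with the smallest p were Pim1 (0.81 ± 0.19), Inhba (0.92 ± 0.26), the secretogranin gene Scg2 (0.92 ± 0.26) and Pcsk1 (1.27 ± 0.36), and none of them passed. With the block 6 lists were called, with cholesterol synthesis lower (median -0.16, adjusted p = 0.0020), postsynaptic genes (adjusted p = 0.016) and glutamate receptors (adjusted p = 0.034) in addition, all with 0.63 with an estimated correlation. The list count was 6 without sham dish 3, 7 without dish 1 of the 24 h group and 1 without its dish 3.

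From 3 h to 24 h after stimulation 49 genes changed, 12 higher and 37 lower. The count was 1 with only the 6 compared arrays, 75 without the 30% of genes with the lowest mean, 95 after quantile normalization, 872 with all 18 arrays in 1 model and 2829 with array weights. Tnfaip6 (-2.54 ± 0.36), Gadd45b (-2.43 ± 0.14, adjusted p = 0.0010), the cytokine gene Tslp (-1.88 ± 0.26), Cwc25 (-1.85 ± 0.19) and Gprc5a (-1.79 ± 0.15) had the largest falls. Dbp (1.57 ± 0.21, adjusted p = 0.038), Chst12 (1.05 ± 0.11), Gimap6 (0.99 ± 0.11), Pdgfrb (0.77 ± 0.10) and Oxsm (0.59 ± 0.09) had the largest rises. Homer1 fell (-0.91 ± 0.13, adjusted p = 0.045); Arc (-1.37 ± 0.25) passed with the replicate block alone (adjusted p = 0.077, and 0.012 with the block), and Fos (-2.49 ± 0.54, adjusted p = 0.12) and Per1 (-1.01 ± 0.22, adjusted p = 0.12) passed in neither fit. Bdnf (-0.66 ± 0.20), Egr1 (-0.63 ± 0.28), Nptx2 (-0.44 ± 0.39), Hspa5 (0.06 ± 0.18) and Cirbp (0.16 ± 0.15) did not pass. Of the 215 genes changed at 3 h, 43 changed in the opposite direction by 24 h, where independent lists would share 0.399. Both comparisons share the stimulated dishes, so part of the excess may come from these. Simulated arrays without effects gave 0, again with hardly any calls; with the observed effects and 24 h dishes kept at the stimulated level, the mean was 0.02 and the highest 1.

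Immediate early transcription factors fell back (2 of 21, Klf4 by -1.67 ± 0.20 and Junb by -1.72 ± 0.26, and 17 adjusted over the list alone), with a median of -1.34 (camera adjusted p = 2.2e-21; adjusted p = 0.23 with an estimated correlation). Maff (-1.45 ± 0.23) passed with the block alone (adjusted p = 0.057, and 0.032 with the block). Effector genes fell back too (3 of 26, Gadd45b, Homer1 and Pim1, and 14 adjusted over the list alone; median -0.67, camera adjusted p = 1.4e-15; adjusted p = 0.23 with an estimated correlation). Cholesterol synthesis genes shifted down (-0.39, camera adjusted p = 9.0e-09; adjusted p = 0.32 with an estimated correlation; 0 of 19 passed, 5 adjusted over the list alone, and with the block 2 passed). Smaller downward shifts were those of presynaptic genes (-0.11, adjusted p = 9.9e-04), postsynaptic genes (-0.10, 0.0015), neuronal markers (-0.13, 0.0025), glycolysis genes (-0.02, 0.018), cytosolic chaperones (-0.13, 0.026) and markers of striatum and hippocampus (-0.21, 0.027). Markers of dividing cells shifted up (0.26, adjusted p = 0.018). No list was called with an estimated correlation, where the smallest adjusted p was 0.23. After quantile normalization 5 of the 10 lists were called; presynaptic genes (adjusted p = 0.069), neurons (0.061), glycolysis (0.087), cytosolic chaperones (0.061), and striatum and hippocampus (0.053) were lost. With the block 150 genes changed, 38 higher and 112 lower, and 47 of the 49 were among them; camera then called 13 lists, adding interneurons (adjusted p = 0.018), glutamate receptors (0.028) and GABA genes (0.044), with 0.30, 0.27 and 0.27 with an estimated correlation. Without dishes 1, 2 and 3 of the 24 h group the count was 1, 19 and 82, and without stimulated dishes 1, 2 and 3 it was 4, 13 and 5.

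The study set stimulated cultures beside sleep-deprived cortex, and 19 genes rose in both, where independent lists would share 0.961 (Fisher's exact test, p = 9.7e-20, genes not being independent). They were Arc, Homer1, Dusp1, Dusp4, Dusp6, Sik1, Gpr3, Nr4a1, Nr4a3, Fosl2, Junb, Per1, Cdkn1a, Errfi1, Lats2, Midn, Rasd1, Stk40 and Tiparp. No gene fell in both (0.742 expected), and Usp2 went in opposite directions (1.796 expected). Across 14807 genes, which are not independent replicates, the responses had a Pearson r of 0.125 (exact permutation p = 0.06, two-sided) and a Spearman rho of 0.127 (p = 0.22); the smallest p the 400 relabellings allow is 0.01. With culture labels exchanged only between dishes of the same number, p was 0.1 and 0.25 (160 relabellings, smallest 0.025). With the culture block 23 genes rose and 6 fell in both. With all 18 arrays in 1 model 3 genes changed in the same direction in both systems, and with array weights 68. This number, of rises and falls together, was 1 without sham dish 1 or 3, 2 without sham dish 2 or stimulated dish 1, 6 and 3 without stimulated dishes 2 and 3, and 10, 9, 12 and 11 without control pool 2 and sleep-deprived pools 1, 2 and 3.

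**Figure D3:**
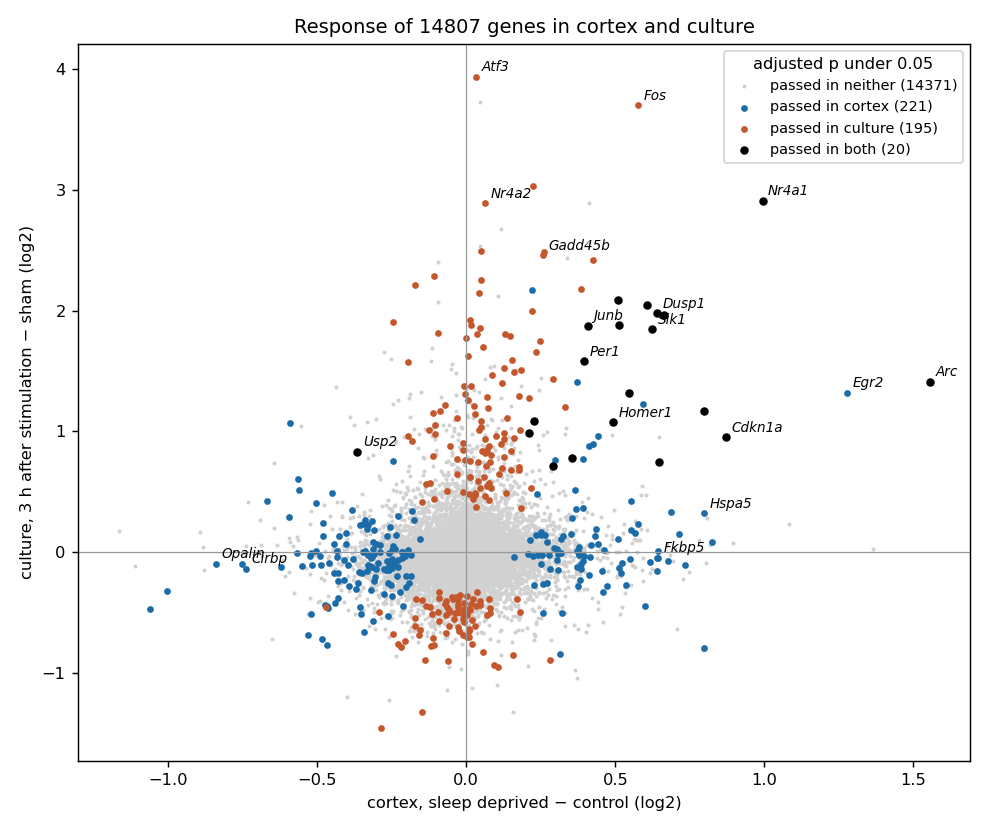
Log2 fold change of 14807 genes after sleep deprivation in cortex (x axis) and 3 h after stimulation in culture (y axis); points are genes, coloured by the comparison in which adjusted p was under 0.05. Of these, 221 passed in cortex alone, 195 in culture alone and 20 in both, 19 of which rose in both.

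Whether a gene responded differently in the systems was tested as an interaction, given as the culture response minus the cortex response. It was called for 307 genes, 166 positive and 141 negative (514 with the replicate block, 269 and 245, with 281 shared). Atf3 (3.90 ± 0.51, adjusted p = 0.0012), Fos (3.12 ± 0.59, adjusted p = 0.013), Nr4a2 (2.82 ± 0.36), Tnfaip6 (2.805 ± 0.40) and the elongation factor gene Ell2 (2.49 ± 0.52) had the largest positive differences. Olfr1444 (-1.59 ± 0.34), the Notch-modifying gene Lfng (-1.48 ± 0.31), Chst12 (-1.18 ± 0.19), Nrarp (-1.17 ± 0.27) and Trp53inp1 (-1.15 ± 0.20) had the largest negative ones. Bdnf (1.06 ± 0.22, adjusted p = 0.019) and Per1 (1.18 ± 0.23, adjusted p = 0.016) responded more in culture. No difference was detected for Arc (-0.14 ± 0.27, adjusted p = 0.97), Egr1 (-0.01 ± 0.30), Nptx2 (1.03 ± 0.42), Dbp (-0.15 ± 0.24) or Hspa5 (-0.48 ± 0.21, adjusted p = 0.36). Homer1 (0.58 ± 0.14, adjusted p = 0.051; 0.029 with the block) and Cirbp (0.60 ± 0.17, adjusted p = 0.10; 0.015 with the block) differed with the block alone.

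Of 26 effector genes, 8 responded more in culture (18 more and 1 less adjusted over the list alone), with a median difference of 0.83 (camera adjusted p = 1.7e-19; adjusted p = 0.077 with an estimated correlation). Gadd45b (2.20 ± 0.16, adjusted p = 1.9e-05) and Pim1 (2.44 ± 0.21) had the smallest p. Of 21 immediate early transcription factors, 11 responded more and 1, Klf10 (-1.01 ± 0.20), less (14 and 1 adjusted over the list alone; median 1.37, camera adjusted p = 2.5e-15; adjusted p = 0.077 with an estimated correlation). Glucocorticoid-responsive genes responded less in culture (median -0.35, camera adjusted p = 4.9e-04; adjusted p = 0.030 with an estimated correlation, 0.095 with the block as well). Of its 21 members Mertk (-0.83 ± 0.13), Plin4 (-0.75 ± 0.15) and Fkbp5 (-0.69 ± 0.15) responded less and Errfi1 (0.77 ± 0.09) more; adjusted over the list alone 9 responded less and 2 more. Endoplasmic reticulum chaperones responded less (median -0.21, camera adjusted p = 0.024; adjusted p = 0.70 with an estimated correlation), with 0 of 24 past limma's test. Cholesterol synthesis genes responded more (0.39, camera adjusted p = 3.5e-06; adjusted p = 0.40 with an estimated correlation), with Pmvk (1.33 ± 0.30, adjusted p = 0.036; 0.057 with the block) of 19. After quantile normalization camera called 6 of the 10 lists; neurons (adjusted p = 0.051), endothelial cells (0.11), inflammatory genes (0.068) and glycolysis (0.12) were lost. With the block camera also called GABA genes (adjusted p = 0.030) and interneurons (0.043), with 0.37 and 0.44 with an estimated correlation. Without culture sham dish 1, camera called 6 lists in place of 10. The count of 307 genes was 537 with only the 12 compared arrays and 1055 with array weights. It was 167, 174 and 202 without control pools 1, 2 and 3, and 172, 159 and 156 without sleep-deprived pools 1, 2 and 3.

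The last comparison described how untreated cultures differed from untreated cortex. The largest falls in culture were those of the transporter gene Slco1a4 (-5.85 ± 0.09), Apod (-5.78 ± 0.22), the myelin genes Mal (-5.24 ± 0.06) and Ermn (-4.88 ± 0.11), and Vtn (-4.98 ± 0.06). Rgs13 (5.36 ± 0.20), the topoisomerase gene Top2a (5.25 ± 0.15), Pclaf (4.98 ± 0.30), B3gnt5 (4.71 ± 0.13) and Prc1 (4.63 ± 0.25) were the most elevated, and Top2a, Pclaf and Prc1 are genes of dividing cells. Adjusted p for these 10 genes was at most 8.1e-10. In all 11287 genes differed, 9028 higher and 2259 lower, with a median of 0.50 over all genes. After quantile normalization that median was 0.034 and the counts were 5069 higher and 4431 lower (53.4% higher in place of 80.0%), so list medians are given relative to all genes.

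**Figure D4:**
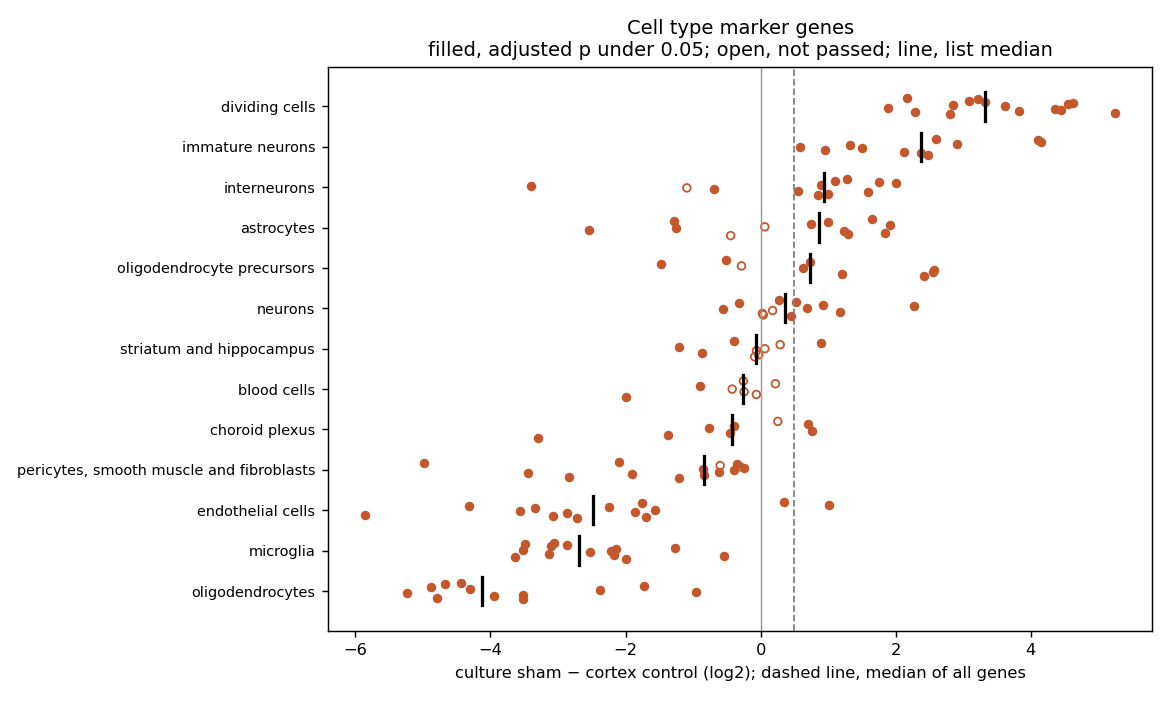
Log2 difference between sham cultures and control cortex (x axis) of the markers in 13 cell type lists; points are genes and the dashed line is the median of all genes (0.50). Markers of oligodendrocytes, microglia and endothelial cells lie mostly below it, and markers of dividing cells above it; medians of neurons, astrocytes and oligodendrocyte precursors change sign after quantile normalization.

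Relative to the median of all genes, the list median was -4.62 for oligodendrocytes (12 of 12 lower as deposited), -3.19 for microglia (14 of 14 lower), -2.98 for endothelial cells (12 of 14 lower) and -1.34 for pericytes (12 of 14 lower). These 4 lists were also called with an estimated correlation (camera adjusted p between 4.6e-04 and 0.0069). Astrocyte markers were not called (camera adjusted p = 0.74): 7 of 12 were higher and 3 lower, with a median 0.38 above that of all genes and of -0.052 after quantile normalization. Markers of dividing cells lay 2.83 above the median of all genes (15 of 15 higher, camera adjusted p = 9.9e-05; adjusted p = 0.50 with an estimated correlation) and those of immature neurons 1.88 above it (11 of 11 higher, 0.0096; adjusted p = 0.50 with an estimated correlation). Cholesterol synthesis genes lay 1.48 above it (19 of 19 higher, camera adjusted p = 0.0053, and 0.62 with an estimated correlation). Sqle (2.67 ± 0.19) and Dhcr7 (2.22 ± 0.11) were among those with the smallest p. After quantile normalization 15 of the 19 were higher and 1 lower. Respiratory chain genes (0.61 above, adjusted p = 0.0011), protein synthesis factors (0.75, 0.0051), endoplasmic reticulum chaperones (0.56, 0.0045) and phospholipid genes (0.45, 0.014) were also called higher, none of them with an estimated correlation (0.50, 0.50, 0.56 and 0.50). After quantile normalization their medians were 0.18, 0.39, 0.32 and 0.077, against 0.034 for all genes, so much of these shifts depends on the normalization, and camera called protein synthesis factors alone of the 4 (adjusted p of 0.091, 0.021, 0.091 and 0.43). Blood cells (-0.75, 0.0041), choroid plexus (-0.92, 0.0057), and striatum and hippocampus (-0.56, 0.033) were called lower, with 0.28, 0.12 and 0.50 with an estimated correlation. After quantile normalization their medians were -0.256, -0.374 and -0.66, and camera called none of the 3 (adjusted p of 0.13, 0.17 and 0.064). Of the anchor genes, Hspa5 (1.27 ± 0.15), Cirbp (1.07 ± 0.12), Bdnf (0.67 ± 0.15), Nptx2 (0.84 ± 0.30) and Per1 (0.44 ± 0.16) were higher in culture and Dbp (-0.76 ± 0.17) lower; Nptx2 (-0.024) and Per1 (-0.47) changed sign after quantile normalization. Arc (-0.02 ± 0.19), Homer1 (0.09 ± 0.10; -0.80 and past the test after quantile normalization), Fos (0.83 ± 0.42, adjusted p = 0.082; 0.037 with the block) and Egr1 (0.47 ± 0.21, adjusted p = 0.056; 0.0021 with the block) did not pass. Age, dissociation, pooling and RNA kit all differed between these groups. The width of the value distributions differed too, and separate normalization of the 2 systems, on which the sources are silent, cannot be told apart from these.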

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

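The tests of scale, dilution, vascular cells, oligodendrocyte share and cortex splits with culture labels kept were chosen after the results were seen, and the other splits were planned.

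The responses to sleep deprivation in cortex and to stimulation in culture were tested against each other by an interaction term, which differed from 0 for 307 genes. The genes with the largest differences (culture minus cortex, log2) were Atf3 (3.90), Fos (3.12), Nr4a2 (2.82), Tnfaip6 (2.805) and Ell2 (2.49), and in the other direction Olfr1444 (-1.59), Lfng (-1.48), Chst12 (-1.18), Nrarp (-1.17) and Trp53inp1 (-1.15). Of 31 gene lists, 10 differed in camera, and 6 of them after quantile normalization, which ended the calls of neurons, endothelial cells, inflammatory genes and glycolysis. Median differences were 0.83 for effector genes, 1.37 for immediate early transcription factors, 0.39 for cholesterol synthesis, -0.35 for glucocorticoid-responsive genes and -0.21 for endoplasmic reticulum chaperones. The other 5 had medians near 0: neurons (0.066, adjusted p = 0.011), striatum and hippocampus (8.7e-05, 0.024), endothelial cells (0.063, 0.024), inflammatory genes (0.075, 0.038) and glycolysis (0.010, 0.042). With an estimated correlation these 5 had adjusted p of 0.29, 0.37, 0.29, 0.37 and 0.37. The first 5 had 0.077, 0.077, 0.40, 0.030 and 0.70, and with the replicate block as well no list passed (0.095 for glucocorticoid-responsive genes). Among 8299 probe sets without a single gene symbol, 1 rose in stimulated culture in limma, with 663 at an unadjusted p under 0.05 where 415 would be expected; in sleep-deprived cortex the count was 0, with 510.

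Immediate early and effector genes responded more in culture than in cortex, with a median difference of 1.03 over 47 genes as deposited. A common scale factor is too small to account for it: after scaling each array to one SD the median was 0.83, with quartiles of 0.13 and 1.32. The SDs of the systems are too close for such a factor to remove the difference, so this outcome was set in advance. A scale that differs with signal level was not tested, so an effect of scale in that form stays open. A candidate explanation is dilution of responding cells in cortex by 1 common factor, which would give every gene the same implied share of responding cells. The upper quartile of that share was 4.32 times the lower over 36 genes (95% bootstrap interval 2.97 to 30.7, 2000 resamples), but cell types that respond in different numbers would widen it too, so dilution stays open. The difference of stimulus and of time after its start was not tested.

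Glucocorticoid-responsive genes rose in sleep-deprived cortex, with a median of 0.32, and not as a group in culture. More vascular cells in the sleep-deprived samples would raise their markers as well. The median of 35 endothelial, pericyte and blood markers was however -0.028, with an upper quartile of 0.021. Only 7 of the 35 mark blood cells, and none is a haemoglobin gene, so this median cannot decide whether blood rose. A common scale factor is also too small to account for the difference from culture. The median difference of response was -0.35 as deposited and -0.29 after scaling (quartiles -0.59 and -0.12). A scale that differs with signal level was not tested here either. A hormone signal that is present in the animal and missing from the dish may be involved, but hormone was not measured and this was not tested.

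Opalin and Aspa fell in sleep-deprived cortex. A lower share of oligodendrocytes is an unlikely cause, because the other 10 oligodendrocyte markers had a median of 0.022, with quartiles of -0.12 and 0.064. Regulation of these 2 genes within oligodendrocytes stays open and was not tested.

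Splits of the compared arrays were counted for each comparison. With 3 arrays against 3 there are 10 splits, so no share under 0.05 is possible. The real count and the highest of the other splits were 241 and 0 for sleep deprivation against control (1 of 10 splits as large), 334 and 1 for recovery against sleep deprivation (1), 215 and 0 for stimulation against sham (1), 49 and 0 for 24 h against 3 h (1), and 11287 and 0 for culture against cortex (1). For recovered against control cortex and for 24 h against sham, both counts were 0, so all 10 splits were as large. For the interaction, 3 of 100 drawn splits gave at least 307 genes, the highest being 339. All 3 were among the 10 splits that kept stimulated and sham dishes apart (208 to 339 genes), and splits that mixed those dishes gave at most 5. The share of 3 in 100 is therefore set by the culture response and says nothing about the cortex labels. With the culture labels kept, 7 of the 20 splits of the cortex arrays gave at least 307 genes. The other counts lay between 208 and 626, with a median of 278. Other cortex labels thus gave counts of similar size, so the count of 307 alone does not show a role of the cortex labels. These 20 splits allow no share under 0.05.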

How the results depend on the processing

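The fits with only the compared arrays (except the baseline with its 6 control arrays), the relabelling within pairs, the quantile-normalized lists, and all alternatives for the lists of the baseline and the interaction were chosen after seeing the data; the other alternatives were planned. Of the values of named genes under the alternatives, 5352 kept their direction and side of the threshold. Of the others, 923 no longer passed, 157 newly passed and 6 reversed. Of the counts of genes and the correlation, 80 stayed the same or within 1.5 times, 70 moved and 2 became stronger. Of the counts by direction, 118 stayed and 114 moved. Of the counts of lists 63 stayed and 15 moved, and of the called lists 478 stayed and 104 became weaker. The cause was not tested except where fewer arrays or genes entered the fit. Few arrays limit all calls, and signal over background was not analysed here.

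Leaving out the 30% of genes with the lowest mean gave 380 genes for sleep deprivation against control, 1 for recovered against control, 608 for recovered against sleep-deprived and 75 for 24 h against 3 h. Array weights gave 811, 1, 774, 910 (stimulation against sham), 958 (24 h against sham), 2829 (24 h against 3 h), 1055 (interaction) and 68 genes shared by both systems. All 18 arrays in 1 model gave 31 for sleep deprivation against control, 42 for recovered against sleep-deprived, 1170 for stimulation against sham, 64 for 24 h against sham, 872 for 24 h against 3 h and 3 shared genes. That model gives both systems 1 shared spread per gene. In the separate fits the median standard error was 0.059 in cortex and 0.115 in culture, so a shared spread is too wide for most cortex genes and too narrow for most culture genes. The trend with robust variance gave 1 gene for recovered against control. With only the compared arrays in the fit, sleep deprivation gave 94, recovered against sleep-deprived 182, 24 h against 3 h 1 and the interaction 537.

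Quantile normalization gave 95 genes for 24 h against 3 h, and 5 lists there and 6 in the interaction. It reversed baseline differences of Homer1 (-0.80), Nptx2 (-0.024), Per1 (-0.47), Ggps1 (-0.14), Sel1l (-0.18) and Wfs1 (-0.034); the construction of the method, which moved the median of all genes from 0.50 to 0.034, accounts for a shift in this direction. With an estimated correlation the lists called were 3 for sleep deprivation, 3 for recovered against sleep-deprived, 0 for stimulation, 0 for 24 h against sham, 0 for 24 h against 3 h, 4 for the baseline and 1 for the interaction. In the same order, with 0 for recovered against control, fry called 7, 6, 3, 0, 1, 29 and 3.

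The replicate block gave 140 genes for sleep deprivation, 190 for recovered against sleep-deprived, 358 for stimulation, 150 for 24 h against 3 h, 514 for the interaction, and 6 lists for 24 h against sham. In cortex the arrays share only a number: same-number pairs had correlations of -0.102 to 0.101 over 9 pairs, and different-number pairs -0.140 to 0.116. Not every cortex array correlated best with arrays of its own number. With the block in the culture fit alone 29 genes changed the same way in both systems, in place of 19, and with it in both fits 21. The block moved no other count of genes within a comparison by more than 1.5 times.

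Leaving out each array in turn gave 72 to 182 genes for sleep deprivation, 104 to 215 for recovered against sleep-deprived, 0 for recovered against control, 18 to 72 for stimulation, 0 to 1 for 24 h against sham, 1 to 82 for 24 h against 3 h, 10816 to 10943 for the baseline, 156 to 363 for the interaction and 1 to 16 shared genes. The correlation of responses lay between 0.0933 and 0.135, past the exact permutation test without sham dish 1 (0.126) or 3 (0.135). Lists called numbered 5 to 6, 6 to 8, 0 to 1, 7 to 10, 1 to 7, 7 to 12, 14 to 15 and 6 to 10 in that order.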

Other observations

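No test was added for the values given here, which come from the planned comparisons, and no explanation of them was tested.

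Single genes of receptors, channels and glucose transport also changed in sleep-deprived cortex, without a call of their lists. The GABA receptor subunit gene Gabra4 (-0.24 ± 0.04, SE, n = 3, adjusted p = 0.035) fell, the 1 of 13 measured GABA genes to pass. The AMPA receptor subunit gene Gria4 (-0.21 ± 0.03, adjusted p = 0.024) and the metabotropic receptor gene Grm3 (-0.25 ± 0.04, adjusted p = 0.031) fell of 16 glutamate receptor genes. Of 29 potassium channel genes, Kcnj3 (-0.18 ± 0.03, adjusted p = 0.043) and Kcnh5 (-0.19 ± 0.04, adjusted p = 0.049) fell; adjusted over the list alone 7 were lower and 2 higher. Camera called none of these 3 lists (adjusted p of 0.27, 0.50 and 0.16), nor that of glycolysis and lactate (0.63). The glucose transporter gene Slc2a1 rose by 0.42 ± 0.04 (adjusted p = 0.0056), the 1 of 20 glycolysis and lactate genes to pass, and fell by 0.40 ± 0.04 from sleep deprivation to recovery (adjusted p = 0.0061). Gria4 (0.18 ± 0.03) and Kcnj3 (0.17 ± 0.03) rose again with recovery.

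In stimulated cultures the neurofilament gene Nefl rose by 1.08 ± 0.13 (adjusted p = 0.014), the 1 of 12 neuronal markers to pass, and all 12 lay above 0. The opioid precursor gene Penk rose by 1.91 ± 0.24 (adjusted p = 0.015), the 1 of 9 markers of striatum and hippocampus to pass, and Neurod1, a factor of neuronal differentiation, changed by -0.76 ± 0.14 (adjusted p = 0.048), the 1 of 11 markers of immature neurons. The neuronal glucose transporter gene Slc2a3 rose by 0.89 ± 0.09 (adjusted p = 0.0076), while Slc2a1 (0.89 ± 0.25) passed with the replicate block alone (adjusted p = 0.14, and 0.012 with the block). The choline kinase gene Chka rose by 0.82 ± 0.10 (adjusted p = 0.014), the 1 of 32 phospholipid genes to pass. Kcnf1 (0.95 ± 0.17, adjusted p = 0.042; 0.053 with the block) was the 1 of 29 potassium channel genes. From 3 h to 24 h Slc2a3 (-0.72 ± 0.09, adjusted p = 0.028) and Chka (-0.91 ± 0.10, adjusted p = 0.020) fell, and Slc2a1 (-0.87 ± 0.25) passed with the block alone (adjusted p = 0.22, and 0.018 with the block).

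Nefl (1.04 ± 0.14), Penk (2.15 ± 0.32), Slc2a3 (0.78 ± 0.11) and Chka (0.76 ± 0.11) responded more in culture than in cortex in the interaction test, with adjusted p of 0.0018, 0.0034, 0.0017 and 0.0029. These genes were named because they had risen in culture, and the interaction uses the same culture arrays. Of all 133 genes that rose in culture, 111 were called in the interaction, so these calls add little to the rises in culture.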
